A study of Mus musculus with 12 samples.

How the data were processed

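Nuclei were isolated from frozen left lower lung lobes of C57BL/6 mice, an inbred laboratory strain, and their RNA was sequenced with the 10x Genomics 3' chemistry, which tags each captured molecule with a unique molecular identifier (UMI). The 12 libraries fall into 4 groups of 3: female and male mice on a control diet (10% of calories from fat) or a high-fat diet (HFD, 60% of calories from fat) for 3 months. The labels give a body weight for each library, with some weights shared within a group, but do not state in words that each is a separate mouse. P-values therefore measure the spread between these libraries. The deposited files hold UMI counts per gene and barcode for 33696 genes, as whole numbers, before any selection of barcodes. Per the submitters' processing notes, the authors used fastp 0.23.4, Cell Ranger 8.0.0 and the genome build GRCm39. The annotation release is not given in the sources used here. Gene symbols are those the deposited files pair with their identifiers; 52 symbols occurred more than once and their counts were kept apart by identifier. All 487 genes of the gene lists and all 234 marker genes were found, 7 of them under a synonym.

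Nuclei were called from the raw barcodes. A barcode was kept when its UMI count reached the larger of 500 and the OrdMag value of its library, with at least 300 genes and at most 5% mitochondrial UMIs. The OrdMag value is the 99th percentile of UMI counts among the richest barcodes divided by 10, with their number chosen as Cell Ranger does. Doublets were scored with Scrublet as in scanpy, and the nuclei with the highest scores were removed, at 0.8% for every 1000 nuclei called in a library. Of 51731 called nuclei 2512 were removed in this way and 49219 were used. Barcodes under 50 UMIs were summed per library as a measure of free RNA in the droplets.

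Together with barcodes that other settings kept, 56973 nuclei were clustered with scanpy 1.11.5 (3000 variable genes, 40 principal components, 20 neighbours, Leiden resolution 1.5, leidenalg 0.10.2). Of 46 clusters, 31 were named from marker lists, giving 20 cell classes; a name here means that at least 3 markers of that class were raised over 2-fold in the cluster. In 7 of the 31 none of the 10 leading genes was a marker of the class. Some named clusters also had at least 3 markers of another class raised, such as NK cell markers in the T cell cluster. The other 15 clusters were left unnamed by hand with the clusters in view, most because their leading genes did not bear out a single class. Cluster 43 was left unnamed although B cell genes led it. The 15 include a cluster led by cell cycle genes, a cluster led by haemoglobin genes and clusters that mixed the genes of several classes. Unnamed clusters held 10.4%, 14.1% and 11.4% of nuclei in the female controls 1 to 3, and 8.20%, 6.31% and 36.6% in the male controls. They held 3.62%, 7.22% and 14.0% in the female HFD libraries, and 8.25%, 9.05% and 9.61% in the male HFD libraries. Clusters of raised UMI count within AT1, AT2 and alveolar fibroblast nuclei were kept, and results without those 3 clusters were computed beside the main ones.

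UMI counts were summed per library over all nuclei, and per library and class where at least 30 nuclei were present. A class was tested when every group kept at least 2 libraries. AT1, AT2, alveolar fibroblast and alveolar macrophage nuclei met this. General capillary, aerocyte, B and T cell nuclei, also planned, did not. Ciliated and secretory airway nuclei were added after the data were seen, as the most numerous classes. The sums were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, its filter on low counts, quasi-likelihood F-test, group means without an intercept), with Benjamini-Hochberg adjustment at 0.05. The contrasts were HFD against control in each sex, the difference between those contrasts, and male against female on control diet. Log2 fold changes are given with a standard error (SE) worked back from the test, as the absolute fold change divided by the square root of F. CPM values are given as mean and SD over libraries.

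Of 23 gene lists fixed for lung and for diet, 21 were tested with camera (limma 3.58.1, preset correlation between genes of 0.01), with adjustment over 254 tests in the diet contrasts of the whole lobe and 6 classes. The other 2 hold the Y-linked genes and the genes around X inactivation. Each call was recomputed with the correlation estimated from the data; 54 tests passed with the preset value and 0 with the estimate, whose smallest adjusted p was 0.519. The estimated correlation within the called lists ranged from -0.0434 to 0.867 (median 0.247). Every p with an estimated correlation given beside a list comes from this step. Leaving out each library in turn left 16 of the 54 calls in place every time; where this left 1 library in an arm, it was assumed to vary like the others. Each of these fits applied the filter on low counts anew, so the members of a list that it measured could differ from those of the main fit. For 0 of the 54 called lists did the median or the mean of the members differ in sign from the test. Among lists that were not called, the ribosomal protein list in males had a median of 0.000727 and a mean of -0.00566, and the test gave it as lower. The difference between the sexes was tested per list in the same way over 127 tests, a step added after the diet contrasts were seen.

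Shares of nuclei were compared with an exact two-sided permutation test of the diet difference averaged over the sexes, with diet labels permuted within sex. There are 400 arrangements, so the smallest p is 0.005, and with 20 classes 1 class alone cannot pass the adjustment. Within 1 sex there are 20 arrangements and the smallest p is 0.10. Shares of single libraries have 95% Wilson intervals, and a share of 0 has the upper limit that 3 nuclei would give; both cover counting error only.

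Genes named in the text follow a fixed rule. In each whole-lobe contrast these are up to 10 genes per direction, and in each class up to 5, with the largest change among genes past the threshold, with every library of 1 group above every library of the other and an average of at least 5 on the log2 CPM scale. Gene models without a name and the sex-linked genes were left out of that part. Then come up to 4 members of each list by smallest p, and Xist, Ddx3y, Kdm5d, Uty and Eif2s3y. Where fewer than 5 genes passed, all of these and the 3 genes with the smallest p were named. Members of a list that did not pass the test by themselves are named as examples, chosen by their p after the values were seen; cell class markers in the free RNA were also singled out after their values were seen. Values of some single genes are not reported here. The lists, markers, tests, groups and the first set of alternatives were fixed before the data were examined.

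The pipeline was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. Over all nuclei 0%, 38.8% and 78.8% of genes changed 2-, 4- and 8-fold were recovered in the female contrast (16017 genes), and 1.49%, 37.3% and 65.2% in the male contrast. Without female HFD replicate 1 it was 8.96%, 74.6% and 95.5% in the female contrast (15881 genes). In the single classes, 2.99% to 31.3%, 34.3% to 88.1% and 75.8% to 100% were recovered. False calls were 7 of 85 over all female nuclei, 1 of 70 over all male nuclei and 5 of 124 without female HFD replicate 1. In the single classes they ran from 2 of 85 (male alveolar macrophage) to 16 of 134 (female ciliated), a share above 0.05 in each female class and in male AT2 (7 of 112) and secretory airway nuclei (12 of 133). A class share that was tripled in both sexes in the simulation reached p at most 0.05 in 99% of draws and passed the adjustment over classes in 3%. The spread between libraries was fixed there, and was smaller than in some real groups, such as mesothelial nuclei in male controls. The 99% therefore does not give the recovery at the real spread. Alternatives covered DESeq2 1.42.0 with its size factors, no filter on low counts, the replicate number as a block, the sequencing run as a term, UMI minimums of 1000 and 200, no doublet removal, fits on 1 sex or on the late run alone, and each library left out in turn. The closing section gives their effect. Added after seeing the data were the UMI minimum of 200 and fits without female HFD replicate 1 and male control replicate 3. Of the 12 pairs of libraries within groups, none had counts as close as sampling noise allows (lowest chi-square per degree of freedom 3.76). This argues against repeats of the same library, and each counted as 1 replicate. It cannot tell separate mice from separate preparations of the same mouse. The reference genome at hand was of an earlier build than the authors' and no coordinates were used.

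The libraries were sequenced in 2 runs. All 6 female libraries and male controls 1 and 2 were in the early run; male control 3 and all 3 male HFD libraries were in the late run. The label of male HFD replicate 1 gives the day and month of the late run with another year, which was taken as a typing error; the run term and each statement on run in males rest on that reading. Female mice were 169 days old and male mice 197 days, so sex and age cannot be told apart.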

Results

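The study profiled the lungs of adult male and female mice with and without obesity from a high-fat diet. Body weight at collection was 20.7 ± 1.15 g (SD, n = 3) in female controls, 47.0 ± 2.65 g in female HFD mice, 30 ± 1 g in male controls and 58.3 ± 1.15 g in male HFD mice. Libraries held 2828431 (male control 3) to 30509915 UMIs, and 205 to 9790 nuclei were used from each. Male control 3 was the shallowest by far: the next lowest total was 6608475 UMIs (female control 2) and the next lowest number of nuclei 1977 (male HFD replicate 3). Median UMIs per nucleus ranged from 646 to 3425. In 11 libraries epithelial nuclei formed the largest part. Among the epithelial classes, ciliated cells, which move mucus along the airways, and secretory airway cells were the most numerous. AT1 cells (the flat cells of gas exchange) and AT2 cells (the source of surfactant) came behind them.

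The library labelled female HFD replicate 1 stood apart from all others in its cell classes. Of its 6182 nuclei 1 was epithelial, a share of 0.0162% (95% Wilson interval 0.00286% to 0.0916%), against 48.0% to 79.6% in the other 11 libraries. At a UMI minimum of 200, a setting chosen after the data were seen, it was 0.834% of 9836 nuclei against 40.6% to 85.8%. AT1, AT2 and ciliated nuclei each numbered 0, which allows a share of up to 0.0485%. In their place were mesothelial nuclei (43.2%), the lining of the pleura and other body cavities, B cells (17.2%), interstitial macrophages (12.3%), adipocytes (11.4%) and T cells (6.86%). The interstitial macrophage cluster also had dendritic cell markers raised, such as Clec9a and Flt3. The T cell cluster also had NK cell markers raised, such as Klre1 and Ncr1. Mesothelial clusters 39 and 40 also had adventitial fibroblast markers raised, such as Col1a1 and Dcn, with 86.8% and 68.7% of their nuclei from a single library. In cluster 9, also named mesothelial, the next highest marker list was erythroid. The mesothelial, interstitial macrophage and T cell shares can therefore each hold more than 1 class. Free RNA was measured in barcodes under 50 UMIs. Sftpc, the surfactant protein made by AT2 cells, had 0 of 2360052 UMIs there, which allows up to 1.27 CPM, against 156 to 1294 CPM in the other libraries. Scgb1a1, the main secretory product of club cells, was at 2.97 CPM against at least 1235 CPM. Plin1, a coat protein of fat droplets in adipocytes, was at 139 CPM, and Fabp4, a fatty acid carrier abundant in fat tissue, at 914 CPM. Xist, which is transcribed from the inactive X chromosome, was at 2533 CPM, within the range of the other female libraries. This library is 1 of 3 in the female HFD group.

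**Figure D1:**
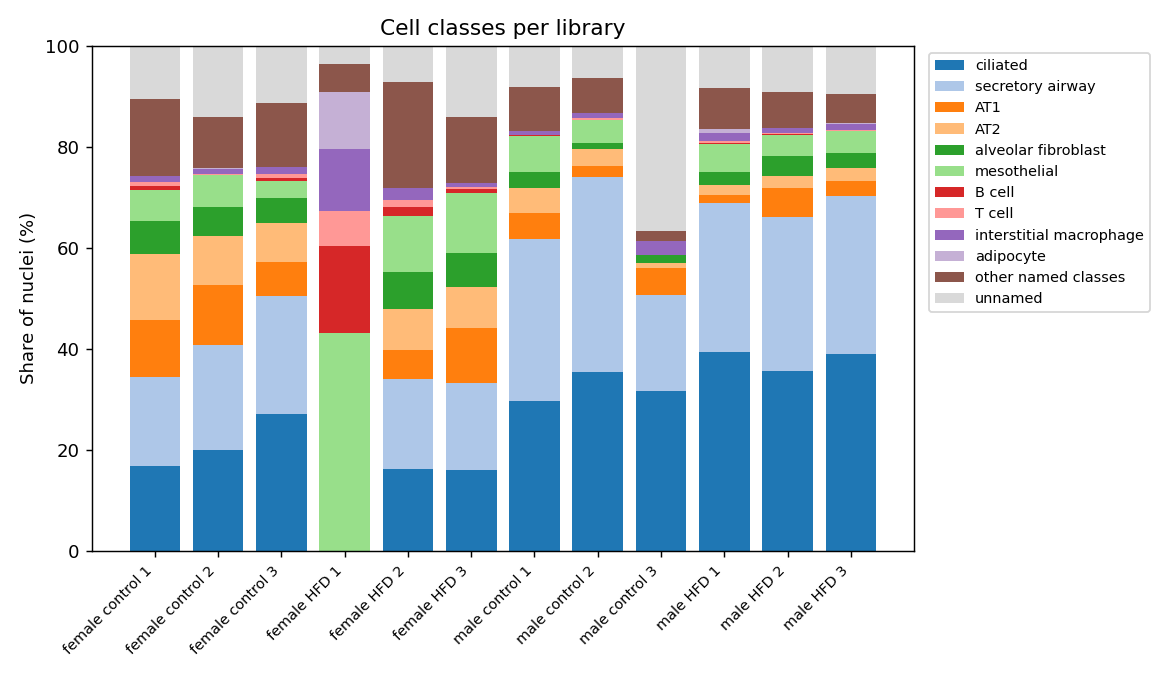
Share of nuclei (%, vertical axis) in each cell class for the 12 libraries (horizontal axis), as stacked bars. Female HFD 1 holds 0.0162% epithelial nuclei, and male control 3, with 205 nuclei, has the largest unnamed share at 36.6%.

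**Figure D2:**
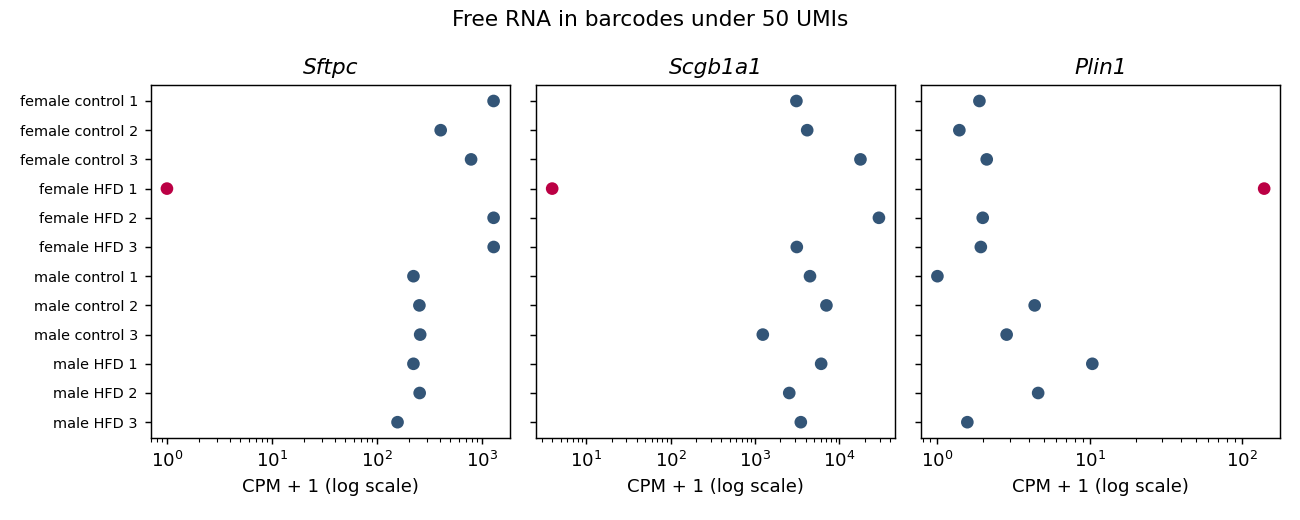
CPM + 1 (log scale, horizontal axes) of Sftpc, Scgb1a1 and Plin1 in barcodes under 50 UMIs, 1 point per library, with female HFD 1 in red. Female HFD 1 lies at 0 CPM of Sftpc, 2.97 CPM of Scgb1a1 and 139 CPM of Plin1, apart from the other 11 libraries in each panel.

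Sex-linked genes followed the sex labels in all 12 libraries. Xist was at 1537 to 2773 CPM in the female libraries and 0 to 1.31 CPM in the male ones. On control diet 5 genes differed between males and females by edgeR, with 566 at an unadjusted p under 0.05 (up to 2144 in other splits of these 6 libraries). Xist was lower in males by a log2 fold change of -11.36 ± 0.58 (SE; 3 and 3 libraries). The others were the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y, at pooled levels of 123, 77.8, 245 and 135 CPM in male controls. Ddx3y and Eif2s3y had 0 UMIs in female controls and were at least 1222-fold and 1337-fold higher in males, against a floor of 3 UMIs over the group. Kdm5d had 3 UMIs and Uty 2 UMIs in female controls, a ratio of 773 (exact 95% interval 264 to 3754) for Kdm5d and 3659 (1012 to 30220) for Uty. DESeq2 called 21 genes. Sex goes with age here, and male control 3 differs in run and depth.

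In females, the question was which genes and cell types differed after 3 months of HFD. Over all nuclei, the genes with the smallest p were Dnajc6, which helps to strip clathrin from vesicles, Has1, a hyaluronan synthase, and Pcnx2. Dnajc6 was at 17.2 ± 6.33 CPM in controls and 95 ± 70.0 CPM in HFD libraries, a log2 fold change of 2.45 ± 0.47. Has1 had a log2 fold change of 2.03 ± 0.41 and Pcnx2 of 2.04 ± 0.42. Female HFD replicate 1 held Dnajc6 at 176 CPM, and the other two at 54.6 ± 4.71 CPM (n = 2). Without it the log2 fold changes were 1.66 ± 0.31, 1.71 ± 0.38 and 1.56 ± 0.35, each with an adjusted p of 0.801 by edgeR. All 3 were higher in each HFD library than in each control, and each had an adjusted p of 0.348 by edgeR (n = 3 and 3). Pcnx2 was among the 10 leading genes of a mesothelial cluster. The female difference in mesothelial share was 16.84 percentage points, and 6.26 without female HFD replicate 1. Mesothelial nuclei were not tested as a class, so cell mix and a change within cells cannot be told apart for these genes. By edgeR 0 of 16017 genes passed the adjustment, with 1654 at an unadjusted p under 0.05. Other splits of the same 6 libraries into 3 and 3 gave up to 2649 of these, and 3 of the 10 splits, diet included, gave at least 1654. DESeq2 called 101 genes, 98 of them higher, among them 6 immediate early genes such as Egr1 and Atf3, the mesothelial markers Lrrn4 and Upk3b, and the B cell markers Bank1 and Ebf1. Without female HFD replicate 1, edgeR called 0 genes with 646 at an unadjusted p under 0.05.

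Over all female nuclei 10 gene lists stood higher under HFD and 3 lower with the preset correlation, and 0 were called with an estimated correlation. Furthest from the rest were the immediate early and dissociation stress genes (in short, immediate early genes), transcription factors and regulators switched on within minutes of a stimulus, tissue handling included, with 22 of 22 members positive and a median log2 fold change of 2.01 (camera adjusted p = 9.94e-14; adjusted p = 0.538 with an estimated correlation). Egr1 had a log2 fold change of 4.51 ± 1.08, Atf3 of 4.16 ± 1.0 and Klf2 of 2.21 ± 0.56. Adjusted over the list alone 15 members passed, and over all genes tested 0 did. Egr1 was at 755 CPM in female HFD replicate 1 and at 29.4 and 94.0 CPM in the other two, against 4.89 to 24.4 CPM in controls. Without that library the list's median was 1.06, and Egr1 was at 2.29 ± 0.60, Atf3 at 2.33 ± 0.67 and Klf2 at 1.21 ± 0.35. MHC class II genes, which present antigen on B cells and macrophages, had 9 of 9 members positive (median 1.62, adjusted p = 5.04e-04; adjusted p = 0.659 with an estimated correlation), 6 of them past the test adjusted over the list alone. H2-Aa was at 95.9 CPM in female HFD replicate 1, the library with 17.2% B cells, and at 16.2 and 12.6 CPM in the other two, against 9.48 ± 1.13 CPM in controls.

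Extracellular matrix genes (24 of 28 positive, median 0.86), with Col3a1 at 2.42 ± 0.79 (0.69 ± 0.40 without female HFD replicate 1), stood higher (adjusted p = 5.04e-04; adjusted p = 0.527 with an estimated correlation). Mesothelial nuclei made up 43.2%, 11% and 11.9% of the female HFD libraries 1 to 3 against 5.22% ± 1.69 of the controls, and adventitial fibroblasts 4.01%, 2.54% and 0.341% against 0.50% to 1.22%. Mesothelial clusters 39 and 40 also had adventitial fibroblast markers raised, the collagen gene Col1a1 among them. Within female alveolar fibroblasts the matrix list was not called (11 of 22 positive, median 0.00, adjusted p = 0.706; adjusted p = 0.902 with an estimated correlation; 1 adjusted over the list alone). Also higher were lipid uptake genes (15 of 18 positive, median 0.60, adjusted p = 0.00102; adjusted p = 0.519 with an estimated correlation), in which Fabp4 was at 541 CPM in female HFD replicate 1, with its 11.4% adipocytes, and at 4.49 to 6.17 CPM in the other two. Glucocorticoid response genes had 15 of 17 members positive (median 0.73, adjusted p = 1.37e-04; adjusted p = 0.538 with an estimated correlation), 2 of them past the test adjusted over the list alone, with Mt2 at 1.65 ± 0.48 and Tsc22d3 at 0.83 ± 0.28 (1.24 ± 0.46 and 0.79 ± 0.29 without female HFD replicate 1). Ribosomal protein genes, a measure of cytoplasmic RNA, had 34 of 38 positive (median 0.38, adjusted p = 2.49e-04; adjusted p = 0.769 with an estimated correlation). These 6 lists kept their calls without each library in turn. Without female HFD replicate 1 the medians were 0.33 for matrix, 0.26 for lipid uptake, 0.42 for glucocorticoid, 0.16 for ribosomal protein and 0.60 for MHC class II genes; without female control replicate 3 the ribosomal median was 0.23. Other splits of the same 6 libraries into 3 and 3 called 6 to 14 lists, against 15 for diet when adjusted within this comparison.

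The other 7 calls over all female nuclei each ended without at least 1 library, and 4 of them without 2 or 3 libraries, each in turn. A call can end with a median about as large, which shows no smaller difference. Where no median is given beside the p of a call that ended without a library, it moved by less than 1.5 times. Surfactant genes, 2 of 17 positive with a median of -0.60 (adjusted p = 0.00179, and adjusted p = 0.694 with an estimated correlation), had a median of -0.19 without female HFD replicate 1 (adjusted p = 0.0809) and -1.09 without replicate 3. Within female AT2 nuclei the surfactant list was not called. The female difference in the share of AT2 nuclei was -4.77 percentage points, and -2.07 without female HFD replicate 1. Fatty acid oxidation and PPAR target genes (28 of 32 positive, median 0.34, adjusted p = 0.0153; adjusted p = 0.794 with an estimated correlation) turned to a median of -0.03 without it (adjusted p = 0.902), and had 0.52 without female HFD replicate 2. Cell cycle genes (18 of 21, median 0.50, adjusted p = 0.00627; adjusted p = 0.694 with an estimated correlation) gave a median of 0.30 (adjusted p = 0.114) without it and 0.21 (0.0506) without female control replicate 3. Insulin and IGF genes (15 of 21, median 0.36, adjusted p = 0.0163; adjusted p = 0.735 with an estimated correlation) gave a median of 0.12 (adjusted p = 0.144) without it and 0.39 (0.0556) without female control replicate 2; without female HFD replicate 2 the median was 0.58. Interferon response genes (25 of 31, median 0.35, adjusted p = 0.0105; adjusted p = 0.794 with an estimated correlation), 1 of them past the test adjusted over the list alone, gave a median of 0.24 (adjusted p = 0.0731) without it and adjusted p values of 0.198 without female HFD replicate 2, 0.182 without female control replicate 3 and 0.0595 at a UMI minimum of 1000. Their median was 0.20 without female control replicate 3 and 0.61 without female HFD replicate 3. Heat shock genes, the chaperones that refold proteins, were lower (2 of 13 positive, median -0.76, adjusted p = 0.0152; adjusted p = 0.769 with an estimated correlation), with an adjusted p of 0.316 without female control replicate 1 (median -0.66) and 0.391 without female HFD replicate 2 (-0.48). The median was -0.77 without female HFD replicate 1 (adjusted p = 3.33e-04). NRF2 antioxidant genes were lower too (5 of 18 positive, median -0.50, adjusted p = 0.0114; adjusted p = 0.715 with an estimated correlation), with a median of -0.31 (adjusted p = 0.281) without female control replicate 1 and -0.22 without female HFD replicate 1. Not called were the NF-kB (adjusted p = 0.0554), oxidative phosphorylation (0.0822), ER stress (0.146), hypoxia (0.154), fatty acid synthesis (0.374), mitochondrially encoded (0.432), cholesterol synthesis (0.505) and clock (0.762) lists.

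**Figure D3:**
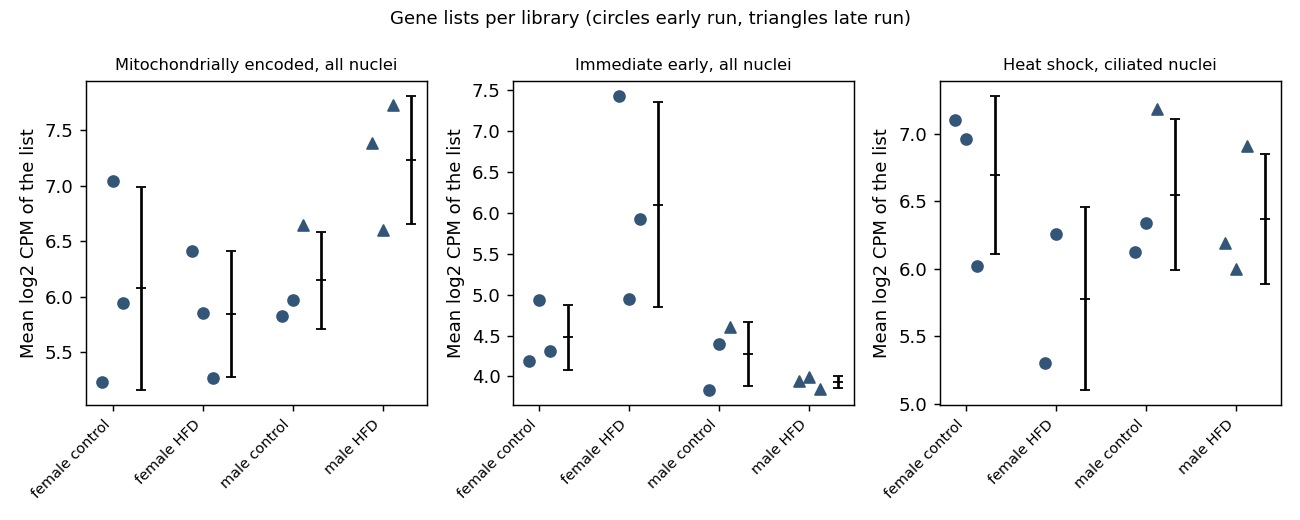
Mean log2 CPM (vertical axes) of the mitochondrially encoded and immediate early lists over all nuclei and of the heat shock list in ciliated nuclei, 1 point per library by group (horizontal axes), circles for the early run and triangles for the late run, with mean and SD beside them. Female HFD libraries lie at 4.95 to 7.43 for the immediate early list, above the female controls at 4.19 to 4.93.

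Within single cell classes female HFD replicate 1 had no epithelial, alveolar fibroblast or alveolar macrophage nuclei to test, so these comparisons set female HFD replicates 2 and 3 against 3 controls. Each of these replicates was also left out, with the other then alone in its arm and assumed to vary like the other libraries. In AT2 nuclei the genes of cholesterol synthesis stood higher as a group, 14 of 14 positive with a median of 0.44 (adjusted p = 1.24e-04; adjusted p = 0.606 with an estimated correlation). Lss had a log2 fold change of 1.09 ± 0.55, Acat2 of 0.90 ± 0.48 and Fdps of 0.86 ± 0.48. The median was 0.08 without female HFD replicate 2 (adjusted p = 0.781) and 0.77 without replicate 3. Heat shock genes stood lower in AT2 nuclei (0 of 6 positive, median -1.19, adjusted p = 1.42e-08; adjusted p = 0.519 with an estimated correlation; 4 past the test adjusted over the list alone), in ciliated nuclei (0 of 9, median -1.06, adjusted p = 8.73e-08; adjusted p = 0.527 with an estimated correlation) and in secretory airway nuclei (0 of 12, median -1.10, adjusted p = 1.12e-08; adjusted p = 0.538 with an estimated correlation). Hspa8, the constitutive HSP70 chaperone, was at 111 ± 57.6 CPM in control and 45.2 ± 30.6 CPM in HFD AT2 nuclei. Heat shock means per library overlapped between the groups in all 3 classes. Without female HFD replicate 2 the medians were -0.59 in AT2 (adjusted p = 0.0639), -0.64 in ciliated (0.0698) and -0.53 in secretory airway nuclei (0.0646), so none of these calls held; without replicate 3 the secretory airway median was -1.65. The same list was lower in AT1 nuclei (0 of 7, median -0.52, adjusted p = 6.69e-04; adjusted p = 0.692 with an estimated correlation), with a median of 0.02 without female HFD replicate 2 (adjusted p = 0.662) and -1.36 without HFD replicate 3. There the adjusted p was 0.147 without female control replicate 1 and the median -1.0 without control replicate 3. It was lower in alveolar fibroblasts (1 of 7 positive, median -0.58, adjusted p = 0.0112; adjusted p = 0.698 with an estimated correlation), with an adjusted p of 0.632 without female HFD replicate 2 (median -0.27), 0.279 without female control replicate 1 (-0.19) and 0.151 without control replicate 2. Its median there was -0.99 without control replicate 3 and -1.09 without HFD replicate 3.

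Immediate early genes stood higher in female alveolar fibroblasts (14 of 15 positive, median 1.19, adjusted p = 1.07e-11; adjusted p = 0.519 with an estimated correlation; 2 past the test adjusted over the list alone). They were also higher in secretory airway nuclei (14 of 17, median 0.84, adjusted p = 3.94e-08; adjusted p = 0.519 with an estimated correlation; 5 adjusted over the list alone). Both calls held without each library in turn, with medians of 0.67 and 0.29 without female HFD replicate 3. They also stood higher in AT2 nuclei (9 of 10, median 0.75, adjusted p = 1.11e-04; adjusted p = 0.606 with an estimated correlation), where the median was -0.10 without female HFD replicate 3 (adjusted p = 0.779) and 0.37 without female control replicate 3. In alveolar fibroblasts Ccn1, a secreted matrix protein, had a log2 fold change of 2.15 ± 0.40, Btg2 of 1.88 ± 0.36 and Egr1 of 2.53 ± 0.49, each with an adjusted p of 0.102 by edgeR. Without female HFD replicate 2, edgeR called 4 genes in this class, these 3 and Rgs2. In free RNA the median log2 difference of the list between female HFD and control libraries was 1.49, and 1.02 without female HFD replicate 1. Genes of the circadian clock were higher in secretory airway nuclei (14 of 19, median 0.35, adjusted p = 7.15e-06; adjusted p = 0.519 with an estimated correlation; 1 adjusted over the list alone), where Hlf was at 2.09 ± 0.60 and Cry2 at 0.80 ± 0.33. The call held without each library in turn, with a median of 0.70 without female control replicate 1. The list holds genes of both arms of the clock, so a call in 1 direction does not give a shift of phase. A phase index, the mean log2 CPM of 10 clock genes such as Nr1d1 minus that of 5 such as Arntl, overlapped between the groups there. It was 0.585 and 0.943 in HFD replicates 2 and 3, and 0.614, 0.756 and -0.879 in controls 1 to 3. The same list was higher in AT2 nuclei (8 of 13, median 0.58, adjusted p = 4.78e-04; adjusted p = 0.519 with an estimated correlation; 2 adjusted over the list alone), with an adjusted p of 0.0705 without female HFD replicate 3 (median 0.38) and a median of 0.31 without female control replicate 3. In alveolar fibroblasts it was higher as well (12 of 15, median 0.41, adjusted p = 0.00343; adjusted p = 0.519 with an estimated correlation; 2 adjusted over the list alone), with an adjusted p of 0.128 without female control replicate 3 and 0.249 without female HFD replicate 3. Extracellular matrix genes were lower in ciliated nuclei (1 of 9 positive, median -0.46, adjusted p = 0.00564; adjusted p = 0.538 with an estimated correlation; 1 adjusted over the list alone), with Thbs1 at -2.62 ± 0.78. The adjusted p was 0.336 without female HFD replicate 2 (median -0.85) and 0.0587 without HFD replicate 3, and the median -1.19 without female control replicate 3.

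The 8 other calls in the same female classes also ended without at least 1 library. Mitochondrially encoded genes were lower in secretory airway nuclei (0 of 12 positive, median -0.68, adjusted p = 5.18e-06; adjusted p = 0.692 with an estimated correlation). The median was -0.16 without female control replicate 2 (adjusted p = 0.0620), -1.09 without control replicate 1 and -1.29 without female HFD replicate 2. They were lower in AT1 nuclei (0 of 10, median -0.27, adjusted p = 0.00478; adjusted p = 0.769 with an estimated correlation). The median was 0.14 without female HFD replicate 3 (adjusted p = 0.844) and -1.10 without HFD replicate 2. Without female controls 1 to 3 it was -0.63, -0.01 (adjusted p = 0.507) and -0.10 (0.107). Glucocorticoid response genes were higher in alveolar fibroblasts (9 of 10, median 0.51, adjusted p = 4.35e-04; adjusted p = 0.606 with an estimated correlation). The median was 0.14 without female HFD replicate 3 (adjusted p = 0.942), 0.20 without female control replicate 3 (0.194) and 1.03 without control replicate 1. In secretory airway nuclei 8 of 11 were positive (median 0.46, adjusted p = 0.00826; adjusted p = 0.538 with an estimated correlation; 1 adjusted over the list alone), with a median of -0.06 without female HFD replicate 3 (adjusted p = 0.478), 0.28 without female control replicate 3 (0.127) and 0.13 without control replicate 2. Matrix genes were lower in secretory airway nuclei (3 of 9 positive, median -0.74, adjusted p = 0.0199; adjusted p = 0.659 with an estimated correlation). The median was -0.28 without female HFD replicate 2 (adjusted p = 0.530) and -0.45 without HFD replicate 3. Without female controls 1 to 3 it was -0.38 (adjusted p = 0.188), -0.58 (0.0648) and -0.42. ER stress genes were lower there (1 of 13, median -0.36, adjusted p = 0.0268; adjusted p = 0.698 with an estimated correlation). The median was -0.19 both without female control replicate 2 (adjusted p = 0.487) and without female HFD replicate 2 (0.564), and -0.61 without HFD replicate 3. At a UMI minimum of 1000 the adjusted p was 0.243. Ribosomal protein genes were higher in ciliated nuclei (25 of 38, median 0.18, adjusted p = 0.00954; adjusted p = 0.698 with an estimated correlation), with an adjusted p of 0.248 without female control replicate 3 and 0.157 without female HFD replicate 3. Fatty acid synthesis genes were lower in alveolar fibroblasts (1 of 9, median -0.27, adjusted p = 0.0285; adjusted p = 0.519 with an estimated correlation). The adjusted p values were 0.0575, 0.0679 and 0.0506 without female controls 1 to 3 (median -0.45 without the third), 0.328 and 0.064 without female HFD replicates 2 and 3 (median -0.18 without the latter) and 0.0817 without male HFD replicate 3.

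In female alveolar macrophages lipid uptake genes were higher (10 of 13 positive, median 0.36, adjusted p = 0.0176; adjusted p = 0.606 with an estimated correlation). Lpl, a lipase that releases fatty acids from lipoproteins, was at 230 ± 30.4 CPM in controls and 340 ± 12.5 CPM under HFD. The call ended without female HFD replicate 2 (median -0.02, adjusted p = 0.993), without female control replicate 1 (0.279) and at a UMI minimum of 1000 (median 0.22, adjusted p = 0.138). Without HFD replicate 3 the median was 0.59. NRF2 antioxidant genes were lower (0 of 6 positive, median -0.45, adjusted p = 0.0152; adjusted p = 0.538 with an estimated correlation). The adjusted p was 0.279 without female control replicate 1 (median -0.29) and 0.0781 without control replicate 2 (-0.22), and 0.627 and 0.167 without female HFD replicates 2 and 3. The call also ended without male controls 1 and 2 and male HFD replicates 1 and 2, each in turn, with medians of -0.32, -0.33, -0.33 and -0.33. Those fits left 1 library in a male group, so the filter on low counts kept more genes. They measured 12 members of the list, with 5, 3, 3 and 5 positive, against 6 in the main fit. A changed set of members therefore cannot be told apart there from the library left out. By edgeR 0 genes passed the adjustment in any female class; at an unadjusted p under 0.05 were 77 in AT1, 120 in AT2, 92 in alveolar fibroblast, 24 in alveolar macrophage, 236 in ciliated and 203 in secretory airway nuclei. DESeq2 called 0 in each. The genes with the smallest p included Txnip (-1.50 ± 0.39) and Sox4 (-1.48 ± 0.43) in AT1, Auts2 (1.31 ± 0.31) in AT2, Tgm2 (1.59 ± 0.42) in ciliated and Depp1 (1.31 ± 0.25, adjusted p = 0.484 by edgeR) in secretory airway nuclei. Tgm2 was at 10.0 ± 2.06 CPM in control and 29.5 ± 4.34 CPM in HFD ciliated nuclei. In free RNA it was higher, at 39.7 CPM in control and 93.7 CPM in HFD libraries, replicate 1 included. Free RNA and ciliated nuclei cannot be told apart as its source.

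In males all HFD libraries and male control 3 came from the late run, and male controls 1 and 2 from the early run. HFD replicate 1 was placed there by the day and month of its label, which gives another year. Mitochondrially encoded genes, whose transcripts lie outside the nucleus and serve here as a measure of RNA quality, were higher over all nuclei, with 13 of 13 positive and a median log2 fold change of 1.32 (adjusted p = 3.17e-18; adjusted p = 0.519 with an estimated correlation). Adjusted over the list alone 6 members passed and over all genes 0. mt-Nd4 was at 108 ± 24.6 CPM in controls and 331 ± 111 CPM in HFD libraries, a log2 fold change of 1.63 ± 0.45. With run as a term the list had a median of 0.80 and an adjusted p of 0.126, while the median over all genes was 0.37. It was higher in all 6 classes, with medians of 0.95 in AT1 (10 of 10 positive, adjusted p = 7.15e-06), 0.69 in AT2 (10 of 10, 8.88e-06), 1.29 in alveolar fibroblast (9 of 9, 2.02e-07) and 1.71 in alveolar macrophage nuclei (8 of 8, 1.12e-08). The median was 1.63 in ciliated (12 of 12, 4.40e-16) and 1.14 in secretory airway nuclei (11 of 12, 2.03e-12). With an estimated correlation the adjusted p was 0.626 in AT1, 0.606 in AT2, 0.538 in alveolar fibroblast, 0.519 in alveolar macrophage and ciliated and 0.527 in secretory airway nuclei. Adjusted over the list alone 1, 2, 0, 5, 10 and 3 members passed in these classes. Without male HFD replicate 1 the AT2 median was 0.36 (adjusted p = 0.0663) and the alveolar fibroblast median 0.85. With run as a term the median was 0.78 in ciliated nuclei (adjusted p = 0.317; all genes 0.54) and 1.66 in secretory airway nuclei (adjusted p = 0.0864; all genes 1.08). In the other classes no male control of the late run had enough nuclei, so run and diet cannot be told apart there.

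Immediate early genes were lower over all male nuclei (5 of 22 positive, median -0.42, adjusted p = 0.00102; adjusted p = 0.794 with an estimated correlation), with Ier3 at -1.02 ± 0.47 and Jun at -1.27 ± 0.66. The adjusted p was 0.00247 with run as a term (median -0.85) and 0.0771 without male control 3. The fit with run as a term rests on male control 3, with 205 nuclei, as the only late-run control. Both values therefore turn on that library. The median was -0.65 without male control 1 and -0.28 without male control 2. Immediate early genes were lower in secretory airway nuclei (4 of 17 positive, median -0.55, adjusted p = 5.18e-06, and adjusted p = 0.521 with an estimated correlation). The adjusted p was 1.57e-04 with run as a term, where male control 3 was again the only late-run control. The median was -0.21 without male control 2 (adjusted p = 0.0504) and -0.32 without male HFD replicate 2. Alveolar fibroblasts had 2 of 15 positive (median -0.57, adjusted p = 0.0273; adjusted p = 0.715 with an estimated correlation). The adjusted p was 0.150 without male HFD replicate 2, 0.0521 without replicate 1 (median -1.05), 0.126 and 0.118 without male controls 1 and 2, and 0.0946 without female control replicate 1. In alveolar fibroblasts extracellular matrix genes were lower (3 of 22 positive, median -0.45, adjusted p = 4.33e-05; adjusted p = 0.519 with an estimated correlation; 4 adjusted over the list alone). The adjusted p was 0.0539 without male control 2 (median -0.33), and the median -0.69 without male control 1 and -0.78 without male HFD replicate 1. Col3a1, a chain of fibrillar collagen, was at 631 ± 54.5 CPM in controls 1 and 2 and 267 ± 74.3 CPM in 3 HFD libraries, and Col1a2 had a log2 fold change of -1.15 ± 0.35. In alveolar macrophages lipid uptake genes were lower (2 of 13 positive, median -0.66, adjusted p = 1.20e-04; adjusted p = 0.519 with an estimated correlation; 1 adjusted over the list alone). The call held without each library in turn, with a median of -1.11 without male control 1. Lpl was at 575 ± 178 CPM in control and 183 ± 77.1 CPM in HFD libraries, and Plin2, a coat protein of lipid droplets, at 429 ± 8.46 and 158 ± 48.2 CPM (n = 2 and 2). Both class results compare early-run controls with late-run HFD libraries.

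Glucocorticoid response genes were higher over all male nuclei (12 of 17 positive, median 0.22, adjusted p = 0.00738; adjusted p = 0.680 with an estimated correlation). The adjusted p was 0.285 without male control 1 (median 0.13) and 0.0572 without male HFD replicate 3 (0.10). It was 0.399 with run as a term, with a median of 0.91 against 0.37 over all genes. That fit rests on male control 3, where 3 of the 17 members had 0 UMIs; the median of the others was 0.18. In AT2 nuclei 6 of 7 were positive (median 0.69, adjusted p = 0.00779; adjusted p = 0.519 with an estimated correlation), with Zbtb16 at 1.45 ± 0.56, a median of 0.38 without male control 1 (adjusted p = 0.0919) and 1.32 without male control 2. In AT1 nuclei 8 of 9 were positive (median 0.58, adjusted p = 0.0174; adjusted p = 0.698 with an estimated correlation), with an adjusted p of 0.0614 without male HFD replicate 2, 0.105 without replicate 3 and 0.476 without male control 1 (median 0.33). Heat shock genes were higher in male AT1 nuclei (7 of 7, median 0.52, adjusted p = 0.0478; adjusted p = 0.794 with an estimated correlation). That adjusted p was 0.0849, 0.150 and 0.263 without male HFD replicates 1 to 3, 0.886 without male control 2 (median 0.09; 0.89 without male control 1), 0.0584 without female control replicate 2 and 0.0506 without female HFD replicate 1. Female HFD replicate 1 was in neither the AT1 nor the alveolar macrophage fit, so without it only the adjustment over tests changed there. Clock genes were higher in male alveolar macrophages (7 of 8, median 0.81, adjusted p = 0.0476, and adjusted p = 0.606 with an estimated correlation). That call ended without each of the 6 female libraries, with adjusted p values of 0.0505 to 0.0893. It also ended without male HFD replicate 1 (median 0.22, adjusted p = 0.548) or 2 (0.191) and without male control 1 (0.0919) or 2 (median 0.31, 0.774). The fits without male HFD replicates 1 or 2 or male control 2 measured 14 members of the clock list, and that without male control 1 measured 13, against 8 with all libraries. Cell cycle genes were higher over all nuclei (15 of 21, median 0.48, adjusted p = 0.00564, and adjusted p = 0.692 with an estimated correlation). Without male control 2 the adjusted p was 0.492 (median 0.40), and 0.116 without male HFD replicate 2 (0.29). It was 0.939 with run as a term and the median 6.44, but 11 of the 21 members had 0 UMIs in male control 3 and the others a median of -0.47. The size of the difference with run as a term was therefore not measurable for this list. Not called over all male nuclei were cholesterol synthesis (adjusted p = 0.138), interferon (0.139), MHC class II (0.293), PPAR targets (0.322), lipid uptake (0.372), extracellular matrix (0.411), surfactant (0.495), ER stress (0.498), NF-kB (0.509), heat shock and ribosomal protein (0.520), NRF2 (0.619), hypoxia (0.676), oxidative phosphorylation (0.761), clock (0.762), and fatty acid synthesis and insulin (0.807).

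Among single genes over all male nuclei, Ogn, a small matrix proteoglycan (1.29 ± 0.32), Dpep1 (1.55 ± 0.40) and Padi2 (1.62 ± 0.43) had the smallest p and adjusted p values of 1 by edgeR. By edgeR 0 genes passed, with 145 at an unadjusted p under 0.05 (up to 331 in other splits of these libraries), and DESeq2 called 0. With run as a term edgeR called 3 genes, and within the late run, against male control 3 alone, 141. That library is single there and was assumed to vary like the others. In the classes edgeR called 0, with 236, 215, 255, 179, 172 and 185 at an unadjusted p under 0.05 in AT1, AT2, alveolar fibroblast, alveolar macrophage, ciliated and secretory airway nuclei (up to 392 and 458 in other splits of the last 2). DESeq2 called 1 gene, in alveolar fibroblasts: Csmd1, a large membrane protein with complement-control repeats, at -3.22 ± 0.60 (adjusted p = 0.173 by edgeR). It passed by edgeR without male control 2, female HFD replicate 2 or female HFD replicate 3, as the single call each time. With run as a term edgeR called 20 genes in secretory airway nuclei.

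The diet differences of the sexes were set against each other directly. For genes the interaction passed for 0 by edgeR over all nuclei (497 at an unadjusted p under 0.05, and up to 2775 in other splits) and 0 by DESeq2; Ccn1 was at -3.86 ± 0.95 and Dnajc6 at -2.76 ± 0.67 (-3.03 ± 0.81 and -1.92 ± 0.44 without female HFD replicate 1), negative values meaning a lower diet difference in males. For lists 34 of 127 tests passed with the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.362), and 29 without female HFD replicate 1 and male control 3, a setting chosen after the data were seen. In AT1, AT2, alveolar fibroblast and alveolar macrophage nuclei neither library was in the fit. Only the adjustment over tests changed in those classes, so this setting tests nothing there. Over all nuclei 12 lists passed when adjusted within this comparison; of 100 splits, the real one included, 16 gave at least 12, and the highest other gave 15. Immediate early genes differed over all nuclei (0 of 22 positive, median -2.23, adjusted p = 3.20e-20; adjusted p = 0.362 with an estimated correlation; median -1.07 without both libraries) and in alveolar fibroblasts (1 of 15, median -1.64, adjusted p = 5.46e-08; adjusted p = 0.362 with an estimated correlation). Heat shock genes differed the other way in AT2 (6 of 6 positive, median 1.23, adjusted p = 9.30e-06; adjusted p = 0.511 with an estimated correlation) and secretory airway nuclei (12 of 12, median 1.31, adjusted p = 5.04e-07; adjusted p = 0.558 with an estimated correlation). Lipid uptake genes differed in alveolar macrophages (2 of 13 positive, median -0.94, adjusted p = 3.23e-06; adjusted p = 0.362 with an estimated correlation). Mitochondrially encoded genes differed over all nuclei (13 of 13 positive, median 1.40, adjusted p = 9.66e-09; adjusted p = 0.558 with an estimated correlation; median 1.97 without both libraries). Run goes with diet in males and not in females, so it enters each of these differences.

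Shares of the cell classes were compared last. Mesothelial nuclei made up 43.2%, 11% and 11.9% of the female HFD libraries and 5.22% ± 1.69 of the female controls, against 3.88% ± 3.64 in male controls and 4.67% ± 0.724 in male HFD libraries. This class can hold more than mesothelial cells, since its clusters 39 and 40 also had adventitial fibroblast markers raised. Averaged over the sexes the difference in mesothelial share was 8.81 percentage points (exact permutation p = 0.045, adjusted p = 0.30) and 3.52 without female HFD replicate 1 (exact permutation p = 0.085). B cells differed by 3.09 points (exact permutation p = 0.015, adjusted p = 0.30) and by 0.454 without that library (exact permutation p = 0.015, adjusted p = 0.20). Adipocytes differed by 2.06 points (exact permutation p = 0.030, adjusted p = 0.30) and by 0.168 without it, and 93.7% of adipocyte nuclei came from it. Ciliated nuclei were 21.3% ± 5.22 of female controls and 10.8% ± 9.35 of female HFD libraries, and 32.3% ± 2.95 and 38% ± 2.02 in males; the difference averaged over the sexes was -2.37 points (exact permutation p = 0.630) and 0.334 without female HFD replicate 1. AT1 nuclei were 9.98% ± 2.89 and 5.54% ± 5.45 in females, and 4.25% ± 1.78 and 3.47% ± 2.15 in males; AT2 nuclei were 10.2% ± 2.78 and 5.40% ± 4.68, and 3.09% ± 2.02 and 2.33% ± 0.268. Without female HFD replicate 1, which held 0 nuclei of these 3 classes, the female HFD shares were 16.2% ± 0.157 (n = 2) for ciliated, 8.31% ± 3.65 for AT1 and 8.11% ± 0.0211 for AT2 nuclei. The female differences then went from -10.5 to -5.09, from -4.44 to -1.67 and from -4.77 to -2.07 points. Of 20 classes 0 passed the adjustment by the exact permutation test, 3 had an unadjusted p under 0.05, and edgeR on the nuclei numbers called 1, the adipocytes. On control diet the measured ciliated shares were higher and the AT1, AT2 and alveolar fibroblast shares lower in each male than in each female (exact permutation p = 0.10, the smallest possible; adjusted p = 0.286). The Wilson intervals of male control 3, with its 205 nuclei, reached the females' shares for ciliated (25.7% to 38.4%, highest female 27%) and AT1 nuclei (3.02% to 9.35%, lowest female 6.67%). For AT2 (0.268% to 3.49%, lowest female 7.68%) and alveolar fibroblast nuclei (0.499% to 4.21%, lowest female 5.13%) they did not.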

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

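The tests of diet loss, of ciliated shares without female HFD replicate 1, of sequencing run, of cytoplasmic RNA, of mitochondrial free RNA, of female HFD replicate 1 alone, of clock phase and of splits for diet by sex lists, and the bounds for listing unnamed clusters, were chosen after the result was seen. For sequencing run, mitochondrial free RNA and female HFD replicate 1 alone, bounds were also changed after the value was seen.

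Ciliated nuclei were lower in each female HFD library and higher in each male HFD library than in the controls of the same sex. The difference between both diet differences was 16.24 percentage points (exact permutation p = 0.005, the smallest possible; adjusted p = 0.10). Female HFD replicate 1 held 0 ciliated nuclei, and without it the value was 10.84 points (exact permutation p = 0.015; adjusted p = 0.30). The other female HFD libraries, at 16.3% and 16.1%, lay close to the lowest control at 16.8% (95% Wilson interval 16.1% to 17.6%). In males the margin was narrow too, with HFD replicate 2 at 35.7% (33.7% to 37.8%) and male control 2 at 35.5% (34.03% to 36.95%), and all male HFD libraries were late-run. Unnamed cluster 0, whose highest marker list was ciliated (mean log2 fold 0.58), held 33.2% of male control 3 and at most 6.99% of each other library. Unnamed cluster 44, led by Csmd1, Pdzrn4 and Col24a1, held 2.006% of nuclei in female HFD replicate 1 (124 nuclei) and 0.491% in replicate 2, against at most 0.0242% in a control. Unnamed cluster 45 held 2.238% of nuclei in female HFD replicate 2 (164 nuclei) and 0 in each other library. It was led by Car12, a carbonic anhydrase, Trp63, a transcription factor of basal epithelial cells, and Krt13, Krt4 and Dsg3, keratins and an adhesion gene of stratified epithelium, and Krt13 was at 69.5 CPM in the free RNA of that library.

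The library labelled female HFD replicate 1 held almost no epithelial nuclei. Epithelial nuclei lost under the UMI minimum are argued against by the free RNA, where epithelial markers took 0.07606 of their share in the lowest other female library; at a UMI minimum of 200 epithelial nuclei were 0.834% there and at least 40.6% elsewhere. Loss of epithelium under diet is argued against as a general effect, since the lower of the other female HFD libraries kept 0.8157 of the epithelial share of the lowest control. A male mouse under a female label is argued against by Y-linked genes at 0.0005911 of the lowest male library. Adipocyte markers took 10.89 times the share of free RNA of the highest other library, which is consistent with tissue other than lung lobe in the sampled piece; this is a hypothesis.

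Mitochondrially encoded genes were higher in male HFD libraries. More cytoplasmic RNA is argued against, since the median of the ribosomal protein list was 0.0005511 of that of the mitochondrial list. Free RNA stays open: 1 of 3 male HFD libraries had a higher mitochondrial share of free RNA (1.80%, 0.929% and 0.699%) than both early-run controls (0.529% and 1.07%), and all 3 lay above male controls 1 and 3 (0.529% and 0.278%); by the bound first set this counted against free RNA. Sequencing run stays open too: male control 3, with 205 nuclei, lay 0.561 of the way from the early-run controls to the HFD mean, first read in favour of run. Its list mean of 6.65 (log2 CPM) lies within the early-run libraries of both sexes (5.23 to 7.05) and above male HFD replicate 2 (6.60), and an effect of diet stays open, untested.

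Immediate early and dissociation stress genes were higher in female HFD libraries. Female HFD replicate 1 alone as the whole cause is argued against: without it 20 of 22 members were positive and the list was still called with the preset correlation. Its median was 0.5299 of its value with all libraries, close to the bound of 0.5 and undecided under the bounds of 0.4 and 0.75 that were also tried. With an estimated correlation the list was not called even with all libraries, and the fit without that library used the preset value only. For free RNA the median change there was 0.8577 of that in alveolar fibroblast nuclei (1.02 against 1.19), between both bounds set, so the 2 cannot be told apart. Clock phase at collection may have differed as well: in 3 of 5 classes each female HFD library had a higher phase index than each control. An earlier form of that test on ciliated and secretory airway nuclei alone went against it, with 0 of 2 classes apart (gaps of -0.321 and -0.171), and handling time and diet itself stay open, untested.

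Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. Over all female nuclei diet gave 0 genes and other splits at most 0, in 10 of 10 splits; for lists it gave 15 and the highest other split 14, with 1 split as large. In males the values were 0 and 0 genes (10 splits), and 4 and 4 lists (4 splits). For sex on control diet they were 5 and 0 genes (1 split). Ciliated male nuclei gave 0 and 0 genes (10 splits) and 1 list against 5 (9 splits), and secretory airway male nuclei 0 and 0 genes (10 splits) and 2 lists against 5 (9 splits). For the diet by sex difference 100 splits were drawn. With 0 genes, the real count is reached by 100 of 100 by construction (highest other 0) and decides nothing. For lists it gave 12 and the highest other split 15, with 16 of 100 as large, so chance cannot be excluded there.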

How the results depend on the processing

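The UMI minimum of 200 and fits without both female HFD replicate 1 and male control 3 were chosen after the data were seen, as were the ciliated and secretory airway classes. Apart from libraries left out, 390 of 409 values of single genes, 179 of 248 of lists, 33 of 35 of shares and 121 of 146 of counts were scored as unchanged. Among the rest, 19 gene values newly passed and 69 list values no longer did. With libraries left out it was 278 of 282, 247 of 324, 84 of 85 and 112 of 115. Where a value moved, the cause was not tested.

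Counts of called genes moved as follows from 0 by edgeR. DESeq2 called 101 over all female nuclei, 21 for sex (5 by edgeR) and 1 in male alveolar fibroblasts. With run as a term, 3 were called over all male nuclei, 1 for diet by sex and 20 in male secretory airway nuclei; within the late run alone, 141 over all male nuclei, with 1 control. Without the filter on low counts, female nuclei gave 5 in AT1, 7 in alveolar fibroblast, 2 in alveolar macrophage, 46 in ciliated and 42 in secretory airway, and male nuclei 3 in alveolar fibroblast, 1 in alveolar macrophage, 31 in ciliated and 9 in secretory airway. On male libraries only, 1 was called in AT1, 7 in AT2, 1 in alveolar fibroblast and 2 in secretory airway nuclei. At a UMI minimum of 200, 1 was called in male alveolar fibroblasts, and with run as a term too, 32 in male ciliated and 2 in male secretory airway nuclei. Leaving out 1 library gave 0 to 4 in female alveolar fibroblasts (4 without female HFD replicate 2), 0 to 1 in male ones and 5 to 8 for sex over all nuclei. For diet by sex it gave 0 to 2 in alveolar fibroblasts and 0 to 1 in AT2 nuclei, and for sex 4 to 13 and 5 to 11 there.

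Lists called numbered 54 of 254 tests, 0 with an estimated correlation, 46 of 186 with run as a term, 50 of 191 at a UMI minimum of 1000 and 57 of 256 without both doubted libraries. Of the 54 calls, 43 could be tested with run as a term and 38 were kept. At a UMI minimum of 1000 it was 43 and 40, and without both doubted libraries 54 and 49. Neither doubted library was in the AT1, AT2, alveolar fibroblast and alveolar macrophage fits, so the calls there were refitted on the same data. Only the adjustment over tests changed for them, and the 49 include calls kept for that reason. Leaving out 1 library gave 49 to 66 calls, of which 39 (without female HFD replicate 2) to 53 were among the 54. With 1 female HFD library left out, the median of the mitochondrial list in female AT1 nuclei ran from -1.1 to 0.142 and that of lipid uptake in female alveolar macrophages from -0.0205 to 0.591. For shares, edgeR on nuclei counts called 1 class (adipocytes, adjusted p = 5.74e-04 by edgeR). The ciliated share difference of -2.365 points turned to 0.7907 at a UMI minimum of 1000 and 0.1902 without both doubted libraries, and ran from -3.742 to 0.3342 with 1 library left out.

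Replicate numbers were shared across groups but did not pair the libraries: 18 same-number correlations ran from -0.443 to 0.208, 4 of them over 0.1, and 3 of 12 libraries correlated best with their own number. With the replicate number as a block, edgeR called 0 genes in each diet contrast and 5 for sex, 55 lists passed (52 of the 54), and 0 share classes did; the block ended the female alveolar macrophage calls of lipid uptake (adjusted p = 0.0852) and NRF2 genes (0.264).

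Run as a term could not be estimated for the male contrast in AT1, AT2, alveolar fibroblast and alveolar macrophage nuclei, and a UMI minimum of 1000 left too few libraries there. Depth limits male control 3 most, with 205 nuclei, and changes of 2-fold were mostly out of reach over all nuclei, where 0% (female, 8.96% without female HFD replicate 1) and 1.49% (male) were recovered in simulation.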

Other observations

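Clock genes differed between female controls. Arntl, which drives the positive arm of the clock, was at 117 CPM in secretory airway nuclei of female control 3 and at 45 and 33.5 CPM in controls 1 and 2. The phase index over all nuclei was -0.80 in female control 3 and 0.16 and 0.19 in the other controls, and 0.42, 0.31 and 0.78 in the female HFD libraries. Unnamed cluster 43, led by the B cell genes Pax5, Cr2 and Bank1, held 0.890% of nuclei in female HFD replicate 1 and at most 0.0266% in a control. Unnamed cluster 38, led by Trp63, a marker of basal airway cells, held 2.35% in male control 2, 1.25% in male HFD replicate 1 and under 1% in each other library. These items were singled out after their values were seen.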
